A study of Oncorhynchus mykiss with 24 samples.

How the data were processed

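Livers of juvenile rainbow trout (Oncorhynchus mykiss, Mt. Shasta strain) were compared on arrays read in 2 colours. Per the labels' protocols, fish ate 1 of 6 test diets or a vehicle diet with 0.15% dimethyl sulfoxide for 12 days and were sampled on day 13, with 2 tanks per treatment and 6 fish per tank. The labels give the test compounds as abbreviations, read here as their usual meanings: 17β-estradiol (E2) at 5 ppm, β-naphthoflavone (BNF) at 500 ppm, indole-3-carbinol (I3C) at 500 or 1500 ppm, or 3,3'-diindolylmethane (DIM) at 500 or 1500 ppm. Each treated RNA was hybridised against a single reference, a pool of liver RNA from 12 vehicle fish, once in each dye. The 24 arrays therefore hold 12 treated RNA samples, 2 per diet, each on 2 dye-swapped arrays. The labels do not say which fish or how many stand behind a treated sample, so p-values measure the spread between these samples, which may be partly technical.

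The authors deposited 1 value per spot and array for 8736 spots, with 0 missing values. Per the labels, scanning used a ScanArray instrument and QuantArray. Background correction, normalisation, log base and ratio direction are not given in the sources used here, and intensities were not used here, so a filter on dim spots could not be run. From the values, all deposited columns but 1 are log ratios. They are taken here as log2: base 10 would need ratios beyond the range of a 16-bit scanner, while a natural log is not excluded and would make every change larger. The remaining column, the first BNF sample with treated RNA in Cy5, is a deposited linear ratio with a median of 1.01 and was converted to log2. The medians of the deposited columns, with that array on the log scale, ran from -0.81 to 1.05, so the arrays were not centred. The number of arrays limits the precision.

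Direction was handled in 2 steps. The labels name Cy3 or Cy5 for the treated RNA but not the numerator, and strong features change sign between the arrays of a swap, so the deposited ratio has a fixed dye direction. A positive value after turning the swap is taken as higher in treated fish. This direction is only likely: its basis is that the labels put Cy3 in channel 1 on every array, so that channel 1 over channel 2 is Cy3 over Cy5. No label states that this was the ratio taken. If Cy5 was the numerator, higher and lower change places throughout. Both arrays of E2 replicate 1 and of DIM 500 ppm replicate 1 ran against the other arrays of their dye orientation, with median correlations over all spots of -0.64, -0.63, -0.56 and -0.71. No label settles the direction of these 4 arrays. The mean of a sample's 2 swapped arrays, in which a treatment effect cancels and dye bias stays, correlated at -0.85 and -0.79 with that of the other samples, against 0.59 to 0.95 for the remaining samples. The 4 arrays were turned for the main values, and every comparison was repeated with the signs as deposited, which gave 2 calls for BNF, 4 for I3C at 1500 ppm and 0 in every other comparison. Only E2 and DIM at 500 ppm hold turned arrays, so in comparisons without them the log2 ratios were unchanged, and calls changed through the spread pooled over all 6 groups. In 20 simulated sets with 2 inverted samples, this rule found exactly those samples in 20. Every simulated array was given the common dye profile of these data after turning. The simulation therefore cannot show whether the real arrays were stored inverted. The turn used the dye component only, not the treatment values. After it, the 2 samples correlated at 0.46 in E2 and 0.85 in DIM at 500 ppm. The diets without turned arrays had 0.16 to 0.75. With signs as deposited, r in E2 and in DIM at 500 ppm would be negative and of the same size. That argues against the deposited signs of the 4 arrays.

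Each array was centred on its median, adjacent duplicate spots were averaged, the dye swap was averaged per sample, and limma 3.58.1 in R 4.3.3 was fitted to 4368 features and 12 samples with 1 mean per group, a pooled spread and empirical Bayes moderation. Adjacent spots were treated as duplicates because their median correlation over the 24 arrays was 0.82, against 0.34 for neighbours of different pairs. The plan made before the data were examined had named uncentred values and single spots as the main choice. Those 2 became alternatives only after the array medians, the spot pairs and counts of calls under several settings had been seen. A call is a Benjamini-Hochberg adjusted p under 0.05. Comparisons with the reference test a mean log2 ratio against 0. The pool counts as 1 control sample, so this test leaves out the control's own spread.

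The reference annotation named 98 spots (49 pairs, 32 symbols, each with 1 symbol), and 8638 spots are unnamed here. Of 33 Entrez genes, 27 were found in the gene table of assembly USDA_OmykA_1.1, which updated hsp90ba to hsp90ab1 and hsc70a to hspa8; no coordinates were printed because the array's files name no build. Of 18 gene lists fixed beforehand, 6 had a measured member and 1, chaperones and folding, had the 5 features needed for limma's camera test (preset correlation 0.01, repeated with an estimated one). Its p was adjusted over the 8 comparisons in which it was run. The other 5 held cyp1a3, pparg, sod1, rps7 and sparc. Named features are, per comparison with the reference, up to 10 higher and 10 lower named features past the threshold with the same sign on all 4 arrays, and up to 5 each way in direct comparisons. Where fewer than 5 passed, those with the smallest p were added. Called features that miss the sign rule at 1500 ppm of I3C and DIM were added after their values had been seen. Signs were counted on single arrays, which still hold the dye bias that averaging the swap reduces. Arrays of unlike sign therefore need not mean that the 2 samples disagree. Unnamed features are limited to 2 higher and 2 lower per comparison.

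The calling step was tested on simulated data over 4368 features with 200 changed. For E2 against the reference it recovered 87.6% of features changed by 1 on the log2 scale and 99.6% of those changed by 2, with 6.12% false among calls. For I3C against DIM at 500 ppm it recovered 60.8% and 96.8%, with 4.02% false. The simulated data held no deviation of the reference pool, so the false share for E2 leaves out any error of the pool. Alternatives tried were uncentred values, scaling between arrays, print-block centring, removal of the common dye profile, single spots, gene averaging, a fit of 24 arrays with a dye term, robust moderation, array weights, only the groups compared, a replicate block, a 2-fold minimum, signs as deposited, and leaving out samples. Without centring, the median log2 ratio of all features shifted to -0.34 for E2, -0.34 for BNF and -0.44 for I3C at 500 ppm, so counts without centring hold that shift.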

Results

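Gene expression in trout liver was measured after 12 days on diets that held a hormone, a synthetic flavone or an indole, on 24 arrays for 12 treated RNA samples, 2 for each of 6 diets. E2 is the main estrogen of vertebrates. BNF is a synthetic flavone that activates the aryl hydrocarbon receptor. I3C is an indole from cruciferous vegetables, and DIM is the dimer that it forms in acid. The series title calls these agents tumor promoters of trout. All samples were set against 1 pool of liver RNA from 12 vehicle fish. Within arrays, the 2 spots of a pair correlated at 0.41 and 0.57 for the first BNF sample and at 0.81 to 0.94 elsewhere. Higher and lower below are in the likely direction only, since the numerator of the ratio is not stated. The arrays of E2 replicate 1 and DIM 500 ppm replicate 1 were turned, and counts with their signs as deposited are given beside each comparison. With those signs the 2 samples of E2, and those of DIM at 500 ppm, ran against each other. Changes then largely cancel in the mean, and the pooled spread rises. Such counts show how far results rest on the turn and cannot show a lack of response.

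The first question was how the liver responded to estrogen. In E2-fed fish the LOC100136761 feature (spots 6030209 and 6030210) was higher, in the likely direction, by 1.58 ± 0.16 (log2 ratio ± SE, n = 2, adjusted p = 2.57e-05), while the 2 other features of that name stood at -0.26 and 0.21. col1a2, a chain of type I collagen, was lower at -0.86 ± 0.15 (adjusted p = 0.00242). The cytosolic chaperone hsp90ab1 was lower at -0.77 ± 0.15 (adjusted p = 0.00492). LOC100135826, listed with the carbonic anhydrase synonym CA2, was at -0.75 ± 0.14 (adjusted p = 0.00394) with the same sign on 3 of 4 arrays, and LOC100136258 at -0.73 ± 0.21 was not called (adjusted p = 0.0651), except with a replicate block. The largest changes lay in unnamed features, at 5.09 ± 0.18 for spots 10020301 and 10020302 and -3.14 ± 0.26 for spots 3010407 and 3010408. limma called 261 of 4368 features, 102 higher and 159 lower. Uncentred values gave 50 higher and 391 lower. Signs as deposited gave 0 calls. The count was 127 without replicate 1 and 156 without replicate 2, where the lone sample is assumed to vary like the other groups. hsp90ab1 lost its call without either sample (adjusted p = 0.127 and 0.0526), col1a2 without replicate 2 (0.0763) and LOC100135826 without replicate 1 (0.113). With the 2 turned samples left out, 112 features were called, without hsp90ab1 (0.203) and LOC100135826 (0.192).

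Among the lists, only chaperones and folding had enough members in E2-fed fish. Its 5 features averaged -0.29, with a median of -0.0030, and the list did not pass limma's camera test over the 8 comparisons in which it was run (unadjusted p of 0.0325, adjusted p = 0.129, and adjusted p = 0.216 with an estimated correlation). Of the 5, 2 passed the threshold over all features, and 2 adjusted over the list alone. Both were hsp90ab1 features, while the remaining hsp90ab1 feature stood at 0.019 and the hspa8 features, a constitutive chaperone, at -0.0030 and 0.052. No member of the estrogen-responsive list was among the named spots. Of the lists with a single gene, pparg, a lipid regulator, stood at -0.11, the sparc features at 0.41 and -0.085, the sod1 features at -0.20 and -0.19, rps7 at -0.039 and cyp1a3 at 0.057 in E2, none of them called.

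**Figure D1:**
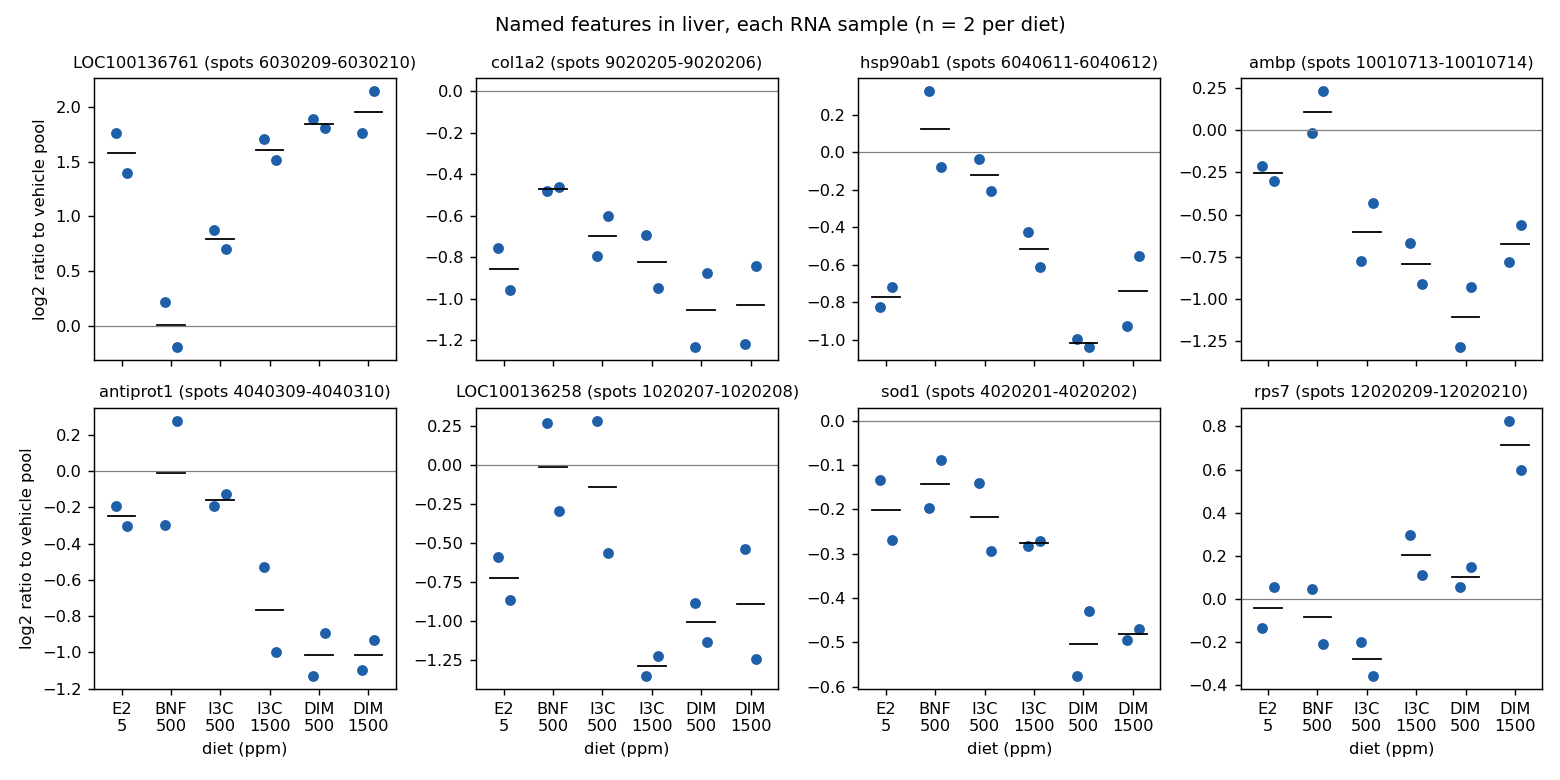
Log2 ratio to the vehicle pool (y axis) of 8 named features for each of the 2 RNA samples per diet (points) with their mean (line), by diet and ppm (x axis). LOC100136761 averaged 0.012 in BNF and 1.58 to 1.95 in E2, I3C at 1500 ppm and DIM.

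BNF tested the response to a receptor agonist of another kind. Exactly 2 features were called, both unnamed and both higher in the likely direction. Spots 10031205 and 10031206 stood at 3.14 ± 0.18 (n = 2, adjusted p = 1.31e-07), and spots 1020303 and 1020304 at 3.12 ± 0.25 (adjusted p = 9.87e-06). The cyp1a3 feature, a cytochrome P450 of the aryl hydrocarbon receptor battery and its sole measured member, was at 0.098 ± 0.17 and was not called. It turned to -0.26 without centring, -0.051 with scaled arrays and -0.12 with the dye profile removed. The named features with the smallest p were col1a2 at -0.47 ± 0.15 (adjusted p = 0.56) and hspa8 at 0.52 ± 0.18 (adjusted p = 0.628), followed by LOC100136015 at 0.23, ambp at 0.17 and LOC100136294 at 0.15. At an unadjusted p under 0.05, limma gave 299 features, more than a share of 0.05 of all features. This test leaves out the spread of the vehicle pool, so that share is not its chance level. The excess therefore does not show a wider response to BNF. Uncentred values gave 41 calls, 2 higher and 39 lower, arrays scaled alike 2 higher and 1 lower, the fit of 24 arrays 6 calls, and leaving out either BNF sample 4. Signs as deposited left the count at 2.

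I3C was given at 500 and 1500 ppm. At 1500 ppm LOC100136761 was higher, in the likely direction, by 1.61 ± 0.16 (n = 2, adjusted p = 1.09e-05), with the 2 other features of that name at 0.017 and 0.013. LOC100136258 was lower at -1.29 ± 0.21 (adjusted p = 0.000828), ambp, the precursor of a plasma protease inhibitor, at -0.79 ± 0.15 (adjusted p = 0.00316), and antiprot1 at -0.76 ± 0.17 (adjusted p = 0.00756). Collagen col1a2 was at -0.82 ± 0.15 (adjusted p = 0.00226) with 3 of 4 arrays of that sign, and LOC100135826 at -0.75 ± 0.14 (adjusted p = 0.00275) with 2 of 4. A second ambp feature was called at -0.73 ± 0.15 (adjusted p = 0.00549) with 3 of 4, and hsp90ab1 at -0.52 ± 0.15 (adjusted p = 0.0466) with 2 of 4. After averaging the swap, both samples were lower for LOC100135826 (-0.63 and -0.86) and for hsp90ab1 (-0.42 and -0.61). That hsp90ab1 call was lost without either sample (0.194 and 0.517), uncentred (0.133), with scaled arrays (0.0572), in the fit of 24 arrays (0.0616), with a replicate block (0.0652), with its features averaged (0.212) and with the 2 turned samples left out (0.0836). limma called 396 features, 156 higher and 240 lower, and uncentred values gave 88 higher and 227 lower. With signs as deposited 4 were called, at unchanged log2 ratios, since no array of this group was turned and only the pooled spread rose. The count was 218 without replicate 1 and 191 without replicate 2. Without replicate 2, ambp (adjusted p = 0.165), antiprot1 (0.372), col1a2 (0.136) and LOC100135826 (0.151) lost their calls, as did the second ambp feature (0.241), and with scaled arrays antiprot1 (-0.65, adjusted p = 0.0849) and the second ambp feature (0.0651) lost theirs.

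At 500 ppm of I3C, LOC100136761 was the sole named feature called, at 0.79 ± 0.16 in the likely direction (n = 2, adjusted p = 0.0357), and it lost the call without either sample (0.171 and 0.19). Its call was also lost uncentred (0.32, adjusted p = 0.285), with scaled arrays (0.77, 0.559), with print blocks centred (0.72, 0.0601), with its features averaged (0.30, 0.32) and with the 2 turned samples left out (0.0513). col1a2 stood at -0.70 ± 0.15 (adjusted p = 0.0543), ambp at -0.61, LOC100135826 at -0.55 and LOC100136295 at -0.44, none of them called. The unnamed spots 10020301 and 10020302 were at 4.39 ± 0.18. limma called 33 features, 18 higher and 15 lower. The count depended on the processing: it was 1 with arrays scaled alike, 61 with the dye profile removed (42 higher and 19 lower), 818 uncentred (9 higher and 809 lower), 250 in a fit of this group alone and 0 with signs as deposited, which left the log2 ratios unchanged. It was 152 without replicate 1 and 16 without replicate 2.

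DIM was given at the same 2 doses. At 500 ppm LOC100136761 was higher, in the likely direction, at 1.85 ± 0.16 (n = 2, adjusted p = 1.6e-06), with the 2 other features of that name at 0.0096 and -0.033. Also higher were fd6d, a fatty acid desaturase, at 0.62 ± 0.17 (adjusted p = 0.0281) and gs04 at 0.62 ± 0.19 (adjusted p = 0.0469). Lower were ambp at -1.11 ± 0.15, hsp90ab1 at -1.06 ± 0.16, col1a2 at -1.06 ± 0.15, antiprot1 at -1.01 ± 0.17, LOC100136258 at -1.01 ± 0.21, LOC100135826 at -0.73 ± 0.14 and sod1, a superoxide dismutase, at -0.50 ± 0.13. Their adjusted p lay between 0.000123 and 0.0219. A second sod1 feature stood at -0.018 and another hsp90ab1 feature at 0.16. limma called 464 features, 143 higher and 321 lower, against 0 with signs as deposited, 860 in a fit of this group alone and 830 with array weights. The split was 227 higher and 391 lower with scaled arrays, 218 and 330 with the dye profile removed and 101 and 232 uncentred. The count was 261 without replicate 1 and 283 without replicate 2. Calls of fd6d (0.561 and 0.127), gs04 (0.183 and 0.651), LOC100135826 (0.101 and 0.0583) and sod1 (0.462 and 0.157) were lost without either sample, that of antiprot1 without replicate 1 (0.0506) and that of LOC100136258 without replicate 2 (0.157). Uncentred, fd6d (0.203), gs04 (0.206) and sod1 (0.296) were not called, gs04 was not with a replicate block (0.0567) or single spots (0.234), and sod1 was not with its features averaged (-0.26, 0.45). With the 2 turned samples left out, fd6d (0.524), gs04 (0.162), LOC100135826 (0.116) and sod1 (0.542) were not called.

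At 1500 ppm of DIM, LOC100136761 was higher, in the likely direction, at 1.95 ± 0.16 (n = 2, adjusted p = 1.05e-06), with the 2 other features of that name at 0.11 and 0.22, and fd6d was higher at 0.63 ± 0.17 (adjusted p = 0.0287). col1a2 was at -1.03 ± 0.15, antiprot1 at -1.02 ± 0.17, LOC100136258 at -0.89 ± 0.21, ambp at -0.67 ± 0.15 and sod1 at -0.48 ± 0.13, with adjusted p from 0.000256 to 0.0303. Other named features were called without the same sign on all 4 arrays. They were the ribosomal protein gene rps7 at 0.71 ± 0.14 (adjusted p = 0.00317), hsp90ab1 at -0.74 ± 0.15 (0.00396) and -0.62 ± 0.16 (0.0188) and a second ambp feature at -0.58 ± 0.15 (0.0243), each with 3 arrays of its sign, and LOC100135826 at -0.51 ± 0.14 (0.0315) with 2. Without replicate 1 none of these 5 was called (0.0733, 0.109, 0.247, 0.185 and 0.214), and uncentred only hsp90ab1 at -0.74 kept its call. The second ambp feature and LOC100135826 also lost theirs without replicate 2 (0.109 and 0.097) and with scaled arrays (0.064 and 0.0524). These 2 and hsp90ab1 at -0.62 also lost theirs with array weights (0.236, 0.212 and 0.144) and in a fit of this group alone (0.15, 0.257 and 0.099), the second ambp feature with print blocks centred (0.0757) and LOC100135826 with the 2 turned samples left out (0.0672). limma called 431 features, 205 higher and 226 lower, and 246 with array weights. Without centring, 116 were higher and 176 lower. Signs as deposited gave 0 calls through the pooled spread, with unchanged log2 ratios. Without replicate 2 the count was 269. Calls of fd6d (0.0806 and 0.37) and sod1 (0.132 and 0.174) were lost without either sample, that of ambp without replicate 1 (0.129) and that of LOC100136258 without replicate 2 (0.45). Uncentred, those of fd6d (0.183), ambp (0.0924) and sod1 (0.448) were lost, and with array weights those of fd6d (0.209), LOC100136258 (0.105), ambp (0.113) and sod1 (0.209). In a fit of this group alone fd6d (0.0885), ambp (0.0532) and sod1 (0.328) were not called, nor were fd6d (0.0756) and sod1 (0.118) with single spots. sod1 was also not called with a replicate block (0.0513), with its features averaged (0.331) or with the 2 turned samples left out (0.0723). For chaperones and folding, limma's camera gave an unadjusted p of 0.0647 and 0.0566 at 500 and 1500 ppm of DIM (adjusted p = 0.129 for each), with 2 of 5 features called at each dose over all features and 2 adjusted over the list alone. For I3C at 500 and 1500 ppm, limma's camera gave an adjusted p of 0.695 and 0.251, with 0 and 1 of 5 called over all features and 0 and 2 adjusted over the list alone, and for BNF 0.291 with 0 called either way.

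**Figure D2:**
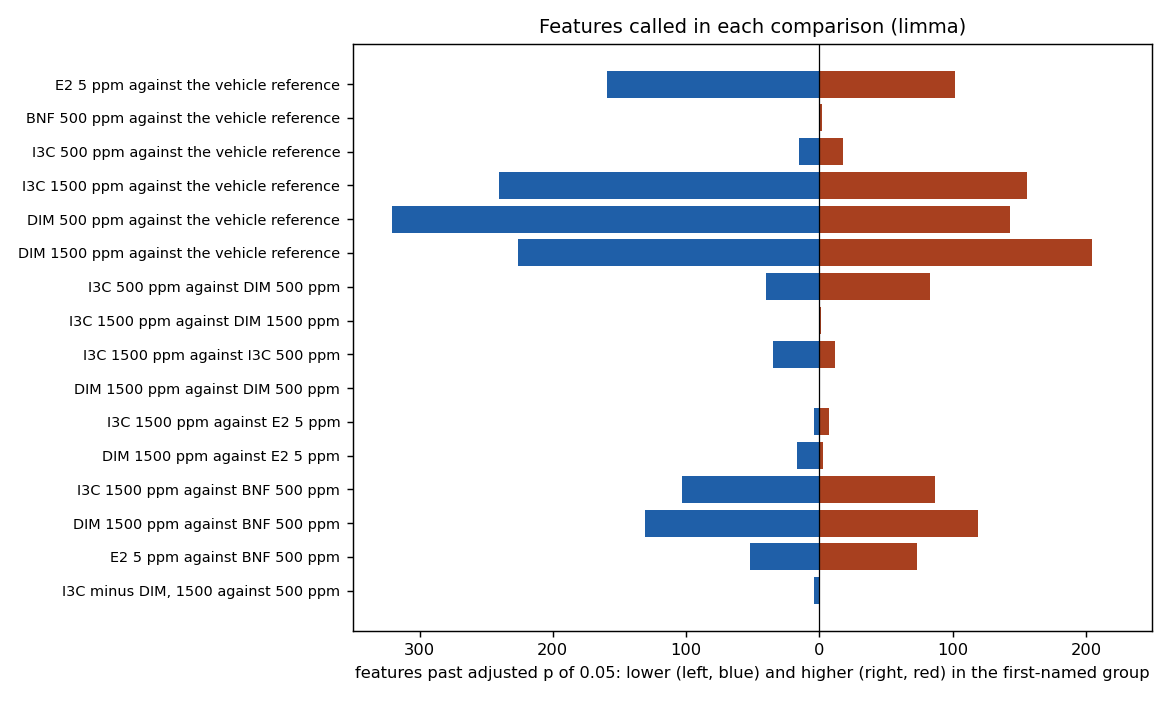
Features past an adjusted p of 0.05 in limma (x axis, bars from 0), higher (right, red) and lower (left, blue) in the first-named group, for the 16 comparisons (y axis). DIM at 500 ppm had 464 and BNF 2.

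I3C and DIM, an indole and its dimer, were compared at matched doses. At 500 ppm LOC100136761 was lower in I3C than in DIM, in the likely direction, by -1.05 ± 0.23 (0.79 against 1.85, adjusted p = 0.019), and hsp90ab1 was higher by 0.90 ± 0.22 (-0.17 against -1.06, adjusted p = 0.0462). antiprot1 (0.85, adjusted p = 0.0792), LOC100136258 (0.87) and the matrix protein sparc (-0.72) were not called. limma called 123 features, 83 higher and 40 lower, while uncentred values gave 24 higher and 81 lower. Of the 123, 122 were called in DIM against the reference, 8 in I3C, and 123 had the smaller absolute change in I3C. The features for chaperones and folding averaged 0.42 for I3C minus DIM, and the list did not pass limma's camera test over the 8 comparisons (unadjusted p of 0.00819, adjusted p = 0.0655, and adjusted p = 0.216 with an estimated correlation), with 2 of 5 called over all features and 2 adjusted over the list alone. The count was 0 with signs as deposited, 42 with the 2 turned samples left out, 198 with array weights, 37 and 47 without DIM replicate 1 or 2, and 49 without I3C replicate 2. hsp90ab1 lost its call uncentred (0.46, adjusted p = 0.408), with a replicate block (0.0581), with single spots (0.0582), with its features averaged (0.61, 0.129) and without any 1 of the 4 samples (0.132 to 0.308). LOC100136761 lost it with its features averaged (-0.31, adjusted p = 0.689), with the 2 turned samples left out (-1.02, 0.181), and without DIM replicate 1 (0.222) or 2 (0.135) or I3C replicate 2 (0.148).

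At 1500 ppm I3C and DIM differed in 1 feature, the unnamed spots 10031205 and 10031206, higher in I3C in the likely direction by 1.63 ± 0.25 (2.93 against 1.30, adjusted p = 0.0476). The call of this feature was lost uncentred (adjusted p = 0.0511), with scaled arrays (0.998), single spots (0.154), array weights (0.315), signs as deposited (0.999) or the dye profile removed (0.069). It was also lost without I3C replicate 1 (0.0542) or 2 (0.392) and without DIM replicate 1 (0.453) or 2 (0.234). The named features with the smallest p were rps7 at -0.51 ± 0.20, LOC100136295 at 0.41, fd6d at -0.45, LOC100136015 at 0.40 and LOC100136761 at -0.34 ± 0.23, with adjusted p = 0.999. For chaperones and folding, limma's camera gave an adjusted p of 0.306. At an unadjusted p under 0.05 there were 86 features, fewer than the share of 0.05 of all features that would pass by chance. Such a shortfall may mean that the test was off its nominal level, and it does not show that the 2 diets were alike. The 95% interval of the difference lay within 1 on the log2 scale for 4153 of 4368 features, and its median half-width was 0.51.

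Dose was compared within each compound. For I3C, 47 features differed between 1500 and 500 ppm, 12 higher and 35 lower in the likely direction, and 46 of the 47 had the larger absolute change at 1500 ppm. The unnamed spots 7040405 and 7040406 were lower by -2.28 ± 0.22 (-2.93 against -0.65, adjusted p = 0.000175). No named feature was called: LOC100136258 stood at -1.15 ± 0.30 (adjusted p = 0.1), LOC100136761 at 0.82 ± 0.23 (0.125), LOC100136295 at 0.83, LOC100136294 at 0.66 and antiprot1 at -0.61. With a replicate block, LOC100136258 was called. The count was 0 with scaled arrays, where spots 7040405 and 7040406 stood at -2.26 (adjusted p = 0.445), and 0 with signs as deposited, where the log2 ratios were unchanged. It was 97 in the fit of 24 arrays, 75 with array weights and 74 with the dye profile removed, and uncentred values gave 38 higher and 12 lower. Without I3C 1500 ppm replicate 1 or 2 it was 15 or 14, and without I3C 500 ppm replicate 1 or 2 it was 145 or 19. For DIM, limma called 0 features between doses and 54 had an unadjusted p under 0.05. That is fewer than the share of 0.05 of all features that would pass by chance. Such a shortfall may mean that the test was off its nominal level, and it does not show that the doses were alike. The median SD between replicates was 0.12 in DIM at 500 ppm and 0.27 at 1500 ppm, while the fit pooled 1 spread. rps7 was at 0.61 ± 0.20, ambp at 0.52, hsp90ab1 at 0.45, LOC100136015 at -0.46 and LOC100136291 at 0.36, with adjusted p = 1. Signs as deposited also gave 0 calls between the DIM doses, and ambp and hsp90ab1 turned to lower there. A fit of the DIM groups alone called 3. The 95% interval lay within 1 for 4049 of 4368 features.

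The difference between I3C and DIM itself depended on dose for 4 unnamed features. The leading one, spots 7040405 and 7040406, stood at -0.65 and -2.93 in I3C and at -3.53 and -3.36 in DIM for 500 and 1500 ppm, an interaction of -2.46 ± 0.31 (adjusted p = 0.00509). No named feature was called, and LOC100136258 came closest with -1.27 ± 0.43 (adjusted p = 0.627), followed by hsp90ab1 at -0.78, LOC100136295 at 0.68, ambp at -0.69 and LOC100136294 at 0.65. The count was 0 with scaled arrays, where the leading feature stood at -3.04 (adjusted p = 0.467), 0 with signs as deposited, 2 with single spots, 14 with the dye profile removed and 23 in the fit of 24 arrays, and uncentred values gave 1 higher and 2 lower. It was 0 without DIM 500 ppm replicate 1, DIM 1500 ppm replicate 2 or I3C 1500 ppm replicate 1, and 1 without DIM 1500 ppm replicate 1 or I3C 500 ppm replicate 1. The leading feature lost its call without DIM 500 ppm replicate 1 (adjusted p = 0.0597), DIM 1500 ppm replicate 2 (0.0512) or I3C 1500 ppm replicate 1 (0.0717).

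The indoles were then set against E2 and BNF. Against E2, I3C at 1500 ppm differed in 11 features (7 higher and 4 lower) and DIM in 20 (3 higher and 17 lower), none of them named. The unnamed spots 2030307 and 2030308 were lower by -2.34 ± 0.28 in I3C and -2.06 ± 0.28 in DIM, in the likely direction, and spots 10031205 and 10031206 were higher by 2.69 ± 0.25 in I3C. For I3C, LOC100136295 stood at 0.75 ± 0.21 (adjusted p = 0.386), LOC100136294 at 0.62, LOC100136700 at -0.75, ambp at -0.54 and antiprot1 at -0.52. For DIM, rps7 stood at 0.75 ± 0.20 (adjusted p = 0.256), antiprot1 at -0.77, LOC100136294 at 0.49, LOC100136295 at 0.47 and LOC100135949 at 0.47. Scaled arrays gave 4 calls for I3C, each higher, and 0 for DIM, with spots 2030307 and 2030308 at -2.12 in DIM (adjusted p = 0.393) and not called in I3C (0.779). The fit of 24 arrays gave 23 and 31, signs as deposited 0 and 0, and array weights 1 for DIM. For I3C, print-block centring gave 5 higher and 6 lower and removal of the dye profile 8 and 8, and uncentred values split DIM into 10 higher and 4 lower. For I3C the count was 19 without E2 replicate 1 and 4 without I3C replicate 1 or 2. For DIM it was 31 and 0 without E2 replicate 1 or 2, and 7 and 9 without DIM replicate 1 or 2. For DIM, spots 2030307 and 2030308 lost their call without E2 replicate 2 (adjusted p = 0.0579) or DIM replicate 1 (0.0574).

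Against BNF, LOC100136761 was higher, in the likely direction, by 1.57 ± 0.23 in E2 (1.58 against 0.012), by 1.60 ± 0.23 in I3C at 1500 ppm and by 1.94 ± 0.23 in DIM at 1500 ppm. It was called in all 3 of these comparisons, but not in I3C with scaled arrays (1.25, adjusted p = 0.0888), nor in E2 (0.44, 0.414) and I3C (0.48, 0.202) when its features were averaged. hsp90ab1 was lower by -0.89 ± 0.21 in E2 (adjusted p = 0.0361) and -0.86 ± 0.21 in DIM (0.0256). LOC100136258 at -1.27 ± 0.30 and ambp at -0.91 ± 0.22 were lower in I3C, and antiprot1 at -1.01 ± 0.24 was lower and rps7 at 0.79 ± 0.20 higher in DIM. In E2, hsp90ab1 lost its call without BNF replicate 1 (0.393) or 2 (0.06) or E2 replicate 1 (0.206) or 2 (0.109), and in DIM without BNF replicate 1 (0.259) or DIM replicate 1 (0.108). In I3C, LOC100136258 lost it without BNF replicate 1 (0.234) or I3C replicate 1 (0.17) or 2 (0.129), and ambp without BNF replicate 1 (0.0976) or 2 (0.186) or I3C replicate 1 (0.0694) or 2 (0.267). In DIM, antiprot1 lost it without BNF replicate 2 (0.269) or DIM replicate 1 (0.076) or 2 (0.0585), and rps7 without BNF replicate 1 (0.0651) or 2 (0.274) or DIM replicate 1 (0.096). Uncentred values ended the calls of hsp90ab1 in E2 (0.327) and DIM (-0.52, 0.504), of LOC100136258 (0.107) and ambp (0.497) in I3C and of antiprot1 in DIM (-0.67, 0.381). Scaled arrays ended those of LOC100136258 (0.159), ambp (0.134), antiprot1 (0.0681) and rps7 (0.49, 0.326), and print-block centring that of ambp (0.0848). In DIM, rps7 was also not called with the dye profile removed (0.59, 0.13), print blocks centred (0.0511), array weights (0.0895), the fit of 24 arrays (0.125), only the groups compared (0.125) or the 2 turned samples left out (0.059). Array weights ended antiprot1 (0.0747) and hsp90ab1 (0.0758) there, and hsp90ab1 was also lost with only the groups compared (0.0718) or its features averaged (0.177). In E2, hsp90ab1 was lost with array weights (0.0511), a replicate block (0.0522), only the groups compared (0.171), its features averaged (0.222) or the 2 turned samples left out (0.333). LOC100135826 at -0.73 and -0.73 and antiprot1 at -0.76 were not called in E2 and I3C, nor were LOC100135949 at -0.64 and LOC100136291, listed with the hemoglobin synonym hbb4, at -0.49 in E2 or ambp at -0.78 in DIM. limma called 125 features for E2 (73 higher and 52 lower), 190 for I3C (87 and 103) and 250 for DIM (119 and 131). Uncentred values gave 47 higher and 18 lower, 91 and 37, and 137 and 45, scaled arrays 47 and 56 for E2 and 32 and 13 for I3C, and removal of the dye profile 79 and 98 for E2 and 96 and 173 for I3C. Signs as deposited gave 0 for each: in E2 LOC100136761 turned to -0.19, while in I3C and DIM the log2 ratios were unchanged and only the pooled spread rose. For E2 the count was 66 and 59 without BNF replicate 1 or 2 and 65 and 82 without E2 replicate 1 or 2. For I3C it was 123 without BNF replicate 1 and 113 and 114 without I3C replicate 1 or 2, and for DIM 161 without BNF replicate 2.

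Whole profiles were compared across features, which are not independent replicates. Pearson's r was 0.80 for E2 and I3C at 1500 ppm, 0.80 for E2 and DIM at 1500 ppm, 0.89 for I3C and DIM at 1500 ppm and 0.59 at 500 ppm. It was 0.065 for E2 and BNF, 0.066 for BNF and I3C and 0.033 for BNF and DIM. The 2 BNF samples correlated with each other at 0.16, against 0.37 to 0.85 within the other diets. That limits how far these low r values can set the BNF profile apart. Unchanged groups that shared a reference varying like a single sample gave a simulated r of 0.67 (0.63 to 0.70 over the draws). The covariance was 0.12, 0.13, 0.17 and 0.081 for the first 4 pairs and 0.0050, 0.0059 and 0.0031 for the BNF pairs, against 0.075 simulated. The BNF pairs share the same pool, and their covariances argue against a pool varying as much as a sample. A smaller part of each r may still come from the shared pool. With signs as deposited r was -0.17 for E2 with I3C, -0.13 for E2 with DIM and -0.15 for I3C with DIM at 500 ppm. It was 0.33 for E2 with BNF, which reverses the order of the E2 pairs. These r use means of E2 or DIM at 500 ppm in which 2 opposed samples largely cancel. They therefore cannot tell whether the responses were alike. Calls were shared by E2 and I3C at 1500 ppm for 83 higher and 121 lower features, where independent lists of those sizes would share 3.64 and 8.74, and by E2 and DIM at 1500 ppm for 92 and 126, against 4.79 and 8.23. No call was shared in either pair with signs as deposited, since E2 had 0 calls. With the 2 turned samples left out, 42 and 49 were shared with I3C and 43 and 50 with DIM, and without centring 40 and 183, and 43 and 154. Without E2 replicate 1 the numbers were 44 and 59, and 45 and 61. Without E2 replicate 2, lower features fell to 66 and 67, and without I3C replicate 1 or 2 those shared with I3C fell to 80 or 73. Array weights left 76 lower features shared with DIM. A 2-fold minimum left 40 and 35 shared with I3C and 44 and 38 with DIM. Counted by single spots, 150 and 202 were shared with I3C and 165 and 219 with DIM. In simulations of such a shared reference with no effect, a group had 162.6 calls and 2 groups shared 54.2 on average, with at most 79 shared. BNF, set against the same pool, had 2 calls.

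**Figure D3:**
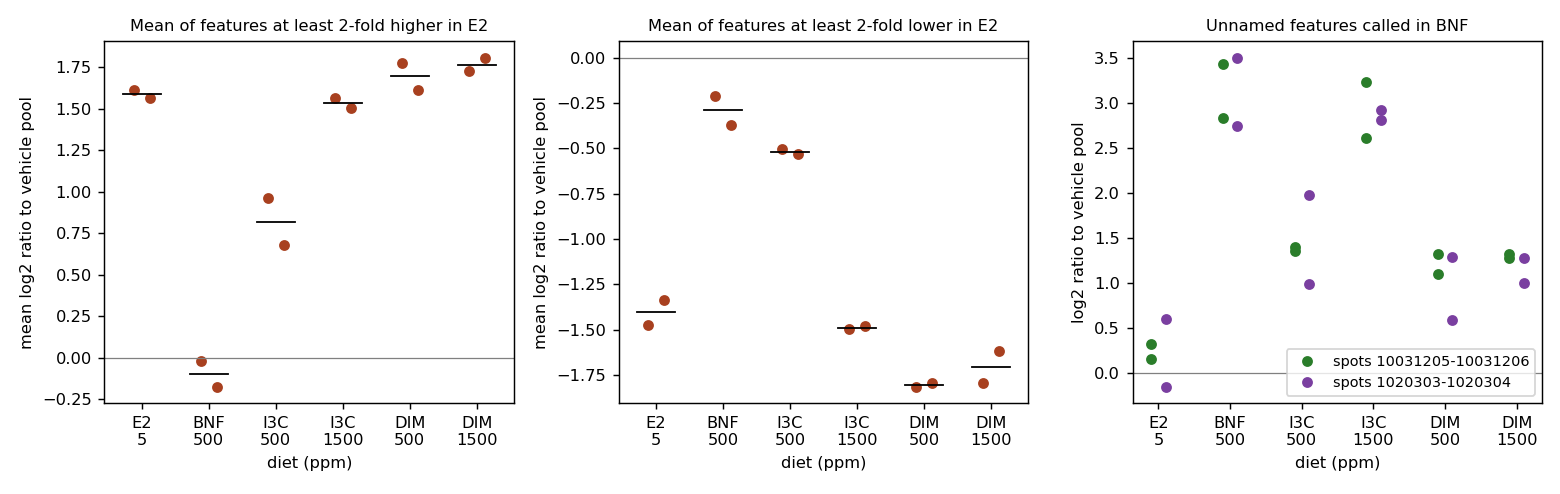
Mean log2 ratio to the vehicle pool of the features at least 2-fold higher (left) or lower (middle) in E2, and the log2 ratio of the 2 unnamed features called in BNF (right), for each RNA sample (points, 2 per diet, with lines for their mean at left and middle) by diet and ppm (x axis). The higher set averaged 1.59 in E2, 1.54 in I3C at 1500 ppm and -0.10 in BNF.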

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

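The tests of the reversed arrays were chosen only after the result was seen, as was the use of feature means, dye profile removal and turned samples for the low count of I3C, and the reading there of scaled arrays and left-out samples, which had been planned as alternatives. Among the 4 arrays of BNF, the SD of the centred values was 0.87 on the highest, apart from the other 3 at the 95% level of Dixon's test, which by chance alone marks about 1 in 20 groups. It lay within the range of the other diets, whose highest array had 0.92.

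The dose dependence of the difference between I3C and DIM passed its test for 4 unnamed features. The interactions were -2.53 for spots 2030307 and 2030308, -1.70 for spots 4020405 and 4020406, -2.46 for spots 7040405 and 7040406 and -1.75 for spots 9031205 and 9031206. For the first, the mean was -0.15 and -2.48 in I3C and -2.41 and -2.21 in DIM at 500 and 1500 ppm. That feature lost its call without DIM 500 ppm replicate 1 (adjusted p = 0.23), DIM 1500 ppm replicate 1 (0.0758) or 2 (0.18), I3C 500 ppm replicate 1 (0.0908) or I3C 1500 ppm replicate 1 (0.131) or 2 (0.0972).

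The 4 arrays of E2 replicate 1 and DIM 500 ppm replicate 1 ran against the others. An opposite response of these fish, or exchanged dye labels, would leave the dye component of a sample as it is in the others, yet it correlated at -0.79 or lower with theirs in both samples. That value argues against both. Ratios stored the other way up would turn both the dye component and the treatment values. Both were seen: after turning, the 2 samples correlated at 0.46 in E2 and 0.85 in DIM at 500 ppm. Such storage remains a candidate explanation that no label settles.

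I3C at 500 ppm had fewer calls than DIM at 500 ppm. As the source of the difference from DIM, a single deviating I3C sample is argued against by the features at least 2-fold higher in E2, whose mean was 0.96 in the higher I3C 500 ppm sample and 1.51 in the lower 1500 ppm sample, and leftover dye bias and unequal array scale by 171 calls with the dye profile removed and 180 with arrays scaled alike, neither below 123. For the count against the reference a deviating sample stays open, since 33 calls became 152 without replicate 1 and 16 without replicate 2, and the 47 calls between the I3C doses became 145 and 19. Beside it, a weaker response to I3C than to DIM at the lower dose may be at work, as a hypothesis from these same data. The calls between I3C and DIM numbered 0 with signs as deposited, 42 with the 2 turned samples left out, and 153 and 49 without I3C replicate 1 or 2.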

How the results depend on the processing

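Signs as deposited, single samples left out for sign or noise, removal of the dye profile, print-block centring, array weights and, as alternatives to centred arrays and averaged pairs, uncentred values and single spots took their roles only after the data were seen. Robust moderation, averaging by gene name and print-block centring left every count of calls within 1.5 times. The filter on values present on all 24 arrays removed nothing, and the filter on dim signal was not run, so what signal over background limits was not tested. In the cases below the cause was not tested, except that a 2-fold minimum lowers a count by construction. Replicate numbers did not pair the samples in 1 direction: deviations of equal-numbered samples correlated between -0.60 and 0.46 over the pairs of groups, from 2 numbers only. The r was positive among E2, BNF and the I3C groups (0.065 to 0.46). It was negative between DIM 1500 ppm and each of these (-0.28 to -0.60). Deviations of the samples may thus not be independent, and a block on the number would not remove that. With the replicate number as a block, the count for I3C 1500 ppm against DIM 1500 ppm was 2, and every other count stayed within 1.5 times. The block ended the calls of hsp90ab1 in I3C 1500 ppm (adjusted p = 0.0652), gs04 in DIM 500 ppm (0.0567), sod1 in DIM 1500 ppm (0.0513), the 2 hsp90ab1 features in I3C 500 ppm against DIM 500 ppm (0.0581 and 0.0523) and hsp90ab1 in E2 against BNF (0.0522), and it brought calls of LOC100136258 in E2 and in I3C 1500 ppm against I3C 500 ppm. Signs as deposited leave log2 ratios unchanged in groups without turned arrays, where counts changed through the pooled spread. Without centring, counts moved to 441 for E2, 41 for BNF, 818 for I3C 500 ppm and 65 for E2 against BNF. With arrays scaled alike, counts moved to 1 for I3C 500 ppm, 248 for I3C 1500 ppm, 4 for I3C 1500 ppm against E2 and 45 for I3C 1500 ppm against BNF. They were 0 for I3C 1500 ppm against DIM 1500 ppm, I3C 1500 ppm against I3C 500 ppm, DIM 1500 ppm against E2 and the interaction. In the fit of 24 arrays with a dye term, counts moved to 6 for BNF, 72 for I3C 500 ppm, 2 for I3C 1500 ppm against DIM 1500 ppm, 97 for I3C 1500 ppm against I3C 500 ppm, 23 for I3C 1500 ppm against E2, 31 for DIM 1500 ppm against E2 and 23 for the interaction. That fit estimated a correlation of 0.0083 between the arrays of a sample, so it treated dye-swapped arrays nearly as separate replicates. With only the groups compared in the fit, counts moved to 250 for I3C 500 ppm, 860 for DIM 500 ppm, 3 for I3C 1500 ppm against DIM 1500 ppm, 3 for DIM 1500 ppm against DIM 500 ppm and 41 for E2 against BNF. With a 2-fold minimum added, counts moved to 96 for E2, 10 for I3C 500 ppm, 161 for I3C 1500 ppm, 221 for DIM 500 ppm, 187 for DIM 1500 ppm and 166 for DIM 1500 ppm against BNF. With single spots, counts moved to 444 for E2, 4 for BNF, 691 for I3C 1500 ppm, 836 for DIM 500 ppm, 772 for DIM 1500 ppm, 329 for I3C 1500 ppm against BNF, 421 for DIM 1500 ppm against BNF and 2 for the interaction. They were 0 for I3C 1500 ppm against DIM 1500 ppm. With signs as deposited, counts moved to 4 for I3C 1500 ppm. They were 0 for E2, I3C 500 ppm, DIM 500 ppm, DIM 1500 ppm, I3C 500 ppm against DIM 500 ppm, I3C 1500 ppm against DIM 1500 ppm, I3C 1500 ppm against I3C 500 ppm, I3C 1500 ppm against E2, DIM 1500 ppm against E2, I3C 1500 ppm against BNF, DIM 1500 ppm against BNF, E2 against BNF and the interaction. With the 2 turned samples left out, counts moved to 112 for E2, 21 for I3C 500 ppm, 267 for DIM 500 ppm, 42 for I3C 500 ppm against DIM 500 ppm, 52 for E2 against BNF and 2 for the interaction. With the first BNF sample left out of every fit, counts moved to 4 for BNF, 123 for I3C 1500 ppm against BNF, 66 for E2 against BNF and 1 for the interaction. With the common dye profile removed, counts moved to 61 for I3C 500 ppm, 74 for I3C 1500 ppm against I3C 500 ppm and 14 for the interaction. They were 0 for I3C 1500 ppm against DIM 1500 ppm. Array weights came out equal for the 2 samples of each diet, from 0.52 in DIM 1500 ppm to 1.91 in DIM 500 ppm. They therefore weigh whole diets and not single samples. With array weights, counts moved to 830 for DIM 500 ppm, 246 for DIM 1500 ppm, 198 for I3C 500 ppm against DIM 500 ppm, 75 for I3C 1500 ppm against I3C 500 ppm, 1 for DIM 1500 ppm against E2 and 155 for DIM 1500 ppm against BNF. They were 0 for I3C 1500 ppm against DIM 1500 ppm. Leaving out 1 sample of the groups compared, with the lone sample assumed to vary like the other groups, gave counts of 127 to 156 for E2, 4 for BNF, 16 to 152 for I3C 500 ppm, 191 to 218 for I3C 1500 ppm, 261 to 283 for DIM 500 ppm, 269 to 340 for DIM 1500 ppm, 37 to 153 for I3C 500 ppm against DIM 500 ppm, 0 to 1 for I3C 1500 ppm against DIM 1500 ppm, 14 to 145 for I3C 1500 ppm against I3C 500 ppm, 4 to 19 for I3C 1500 ppm against E2, 0 to 31 for DIM 1500 ppm against E2, 113 to 131 for I3C 1500 ppm against BNF, 161 to 220 for DIM 1500 ppm against BNF, 59 to 82 for E2 against BNF and 0 to 6 for the interaction. With signs as deposited, the profile correlation was -0.17 for E2 and I3C 1500 ppm, -0.13 for E2 and DIM 1500 ppm, 0.33 for E2 and BNF and -0.15 for I3C 500 ppm and DIM 500 ppm. With the 2 turned samples left out, the profile correlation was 0.64 for E2 and I3C 1500 ppm and 0.54 for I3C 500 ppm and DIM 500 ppm. With the common dye profile removed, the profile correlation was 0.14 for BNF and I3C 1500 ppm. Over features called in either group, the profile correlation was 0.89 for E2 and I3C 1500 ppm, 0.25 for BNF and I3C 1500 ppm and 0.81 for I3C 500 ppm and DIM 500 ppm. With Spearman's rho, the profile correlation was 0.64 for E2 and I3C 1500 ppm, 0.58 for E2 and DIM 1500 ppm, -0.17 for BNF and I3C 1500 ppm, 0.45 for I3C 500 ppm and DIM 500 ppm and 0.70 for I3C 1500 ppm and DIM 1500 ppm. Leaving out 1 sample gave correlations of 0.64 to 0.76 for E2 and I3C 1500 ppm, -0.00083 to 0.13 for BNF and I3C 1500 ppm, -0.17 to 0.25 for BNF and DIM 1500 ppm, 0.47 to 0.60 for I3C 500 ppm and DIM 500 ppm and 0.75 to 0.85 for I3C 1500 ppm and DIM 1500 ppm. For the chaperone list, which passed in no comparison after adjustment over the 8, the unadjusted camera test gave p = 0.0653 for E2 without centring, p = 0.072 for E2 with an estimated correlation, p = 0.146 for E2 with features of 1 gene name averaged, p = 0.497 for E2 with signs as deposited, p = 0.983 for I3C 500 ppm with print blocks centred, p = 0.0415 for DIM 500 ppm with arrays scaled alike, p = 0.989 for DIM 500 ppm with signs as deposited, p = 0.0335 for DIM 500 ppm with the common dye profile removed, p = 0.0428 for DIM 500 ppm with print blocks centred, p = 0.0439 for DIM 1500 ppm with the common dye profile removed, p = 0.0211 for DIM 1500 ppm with print blocks centred, p = 0.0654 for I3C 500 ppm against DIM 500 ppm with features of 1 gene name averaged and p = 0.509 for I3C 500 ppm against DIM 500 ppm with signs as deposited. Its direction turned in 3 of these, E2 with signs as deposited, I3C 500 ppm with print blocks centred and DIM 500 ppm with signs as deposited. With signs as deposited, means of feature sets turned to -0.024 in E2 for those higher in E2, -0.080 in DIM 500 ppm for those higher in E2, 0.071 in E2 for those lower in E2 and 0.011 in DIM 500 ppm for those lower in E2. The log2 ratios that turned in E2 with signs as deposited were LOC100136761 -0.18, hsp90ab1 0.053, LOC100135826 0.050, spot 10020301 -0.16, spot 12020713 -0.059, spot 3010407 0.43 and spot 9031205 0.016. The log2 ratios that turned in DIM 500 ppm with signs as deposited were LOC100136761 -0.039, fd6d -0.13, ambp 0.18, hsp90ab1 0.0090, col1a2 0.18, antiprot1 0.12, LOC100135826 0.034, sod1 0.074, spot 12020713 -0.14, spot 7040405 0.022, spot 3010407 0.24, cyp1a3 -0.062 and ambp 0.24. The log2 ratios that turned in I3C 500 ppm against DIM 500 ppm with signs as deposited were hsp90ab1 -0.18, LOC100136761 0.83, hsp90ab1 -0.10, antiprot1 -0.28, LOC100136258 -0.015, spot 7040405 -0.67, spot 4020413 -0.53 and spot 4010307 0.47. The log2 ratios that turned in DIM 1500 ppm against DIM 500 ppm with signs as deposited were ambp -0.81 and hsp90ab1 -0.63. The log2 ratios that turned in E2 against BNF with signs as deposited were LOC100136761 -0.19, LOC100135826 0.071 and spot 10020301 -0.20. The log2 ratios that turned in the interaction with signs as deposited were hsp90ab1 0.29, ambp 0.64, spot 2030307 0.27 and spot 7040405 1.10. Without centring, values turned in E2 (cyp1a3 -0.31, spot 10031205 -0.13, spot 1020303 -0.15), BNF (LOC100136015 -0.13, ambp -0.18, LOC100136294 -0.20, cyp1a3 -0.26) and I3C 500 ppm (cyp1a3 -0.30). Without 1 or the other sample, values turned in E2 (cyp1a3 -0.10 to 0.22, spot 1020303 -0.16 to 0.60), BNF (LOC100136015 -0.038 to 0.49), I3C 500 ppm (cyp1a3 -0.19 to 0.53) and DIM 1500 ppm (cyp1a3 -0.063 to 0.34). With arrays scaled alike, values turned in BNF (cyp1a3 -0.051). With the common dye profile removed, values turned in BNF (cyp1a3 -0.12) and I3C 500 ppm (cyp1a3 -0.11).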

Other observations

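The summary over features selected in E2 was chosen only after the results were seen, as were its repeats under other settings, the test of the BNF response and the test of the cyp1a3 spot pair. The 51 features called and at least 2-fold higher in E2, in the likely direction, averaged 1.59 ± 0.034 there (SD, n = 2), a value raised by their selection. They averaged 1.54 ± 0.043 in I3C at 1500 ppm, 1.69 ± 0.11 and 1.77 ± 0.057 in DIM at 500 and 1500 ppm, 0.82 ± 0.20 in I3C at 500 ppm and -0.10 ± 0.11 in BNF. The 45 features at least 2-fold lower in E2 averaged -1.40 ± 0.10 there, -1.49 ± 0.0096 in I3C at 1500 ppm, -1.80 ± 0.015 and -1.71 ± 0.12 in DIM, -0.52 ± 0.021 in I3C at 500 ppm and -0.29 ± 0.11 in BNF. All groups share the vehicle pool. Under signs as deposited E2 had 0 calls, and the higher and lower set averaged -0.024 and 0.071 in E2 and -0.080 and 0.011 in DIM at 500 ppm. Uncentred, the higher and lower set averaged 1.22 and -1.77 in E2, 0.35 and -0.99 in I3C at 500 ppm and -0.45 and -0.64 in BNF, each shifted down. Called alike in E2, both I3C doses and both DIM doses were 14 higher and 14 lower features. More were shared when I3C at 500 ppm was not required. Of features called in E2, I3C at 1500 ppm and both DIM doses alike, 82 were higher and 117 lower in all 4, against 0 and 0 with signs as deposited, 39 and 49 with the 2 turned samples left out, 40 and 142 uncentred and 44 and 59 without E2 replicate 1. The lower ones numbered 63 without E2 replicate 2, 76 and 72 without I3C 1500 ppm replicate 1 or 2 and 75 with array weights.

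The 2 features called in BNF had another order across diets. Spots 10031205 and 10031206 stood at 3.14 in BNF, 2.93 in I3C at 1500 ppm, 1.38 in I3C at 500 ppm, 1.21 and 1.30 in DIM at 500 and 1500 ppm and 0.24 in E2. Spots 1020303 and 1020304 stood at 3.12, 2.87, 1.48, 0.94, 1.14 and 0.22 in the same order. Both were selected by their call in BNF, which raises their BNF values. In limma, I3C at 1500 ppm against BNF was not called for either. The first stood at -0.21 ± 0.25 (adjusted p = 0.702) and the second at -0.25 ± 0.36 (0.753). Spots 10031205 and 10031206 were called in every I3C and DIM group, except with scaled arrays in I3C at 500 ppm (adjusted p = 0.439). Spots 1020303 and 1020304 were called there too, but scaled arrays ended the call in I3C at 500 ppm (0.559) and in DIM at 500 and 1500 ppm (0.104 and 0.0542), print-block centring that in DIM at 500 ppm (0.0606) and array weights that in DIM at 1500 ppm (0.0997). It was also lost without I3C 500 ppm replicate 2 (0.321), DIM 500 ppm replicate 2 (0.667) or DIM 1500 ppm replicate 1 (0.0589) or 2 (0.205). In I3C at 500 ppm and in DIM, signs as deposited left neither feature called. Neither was called in E2, where uncentred values turned them to -0.13 and -0.15, and the second turned to -0.16 without E2 replicate 2.

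The cyp1a3 feature gave no call in BNF. A lack of any response of these livers to BNF is argued against by the 2 called features, the smaller at 3.12. Weak signal of the spots stays open: the 2 spots of the pair correlated at 0.39 over the 12 samples, against a median of 0.73 over all pairs, which lies between the bounds set for the test. Different clones with 1 gene name also disagreed, as 2 other LOC100136761 features stood at -0.26 and 0.21 in E2 beside 1.58.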
